A study of Danio rerio with 12 samples.

How the data were processed

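Total RNA from adult zebrafish was measured on 12 Affymetrix zebrafish GeneChip arrays with biotin-marked targets, per the labels. There was 1 array of brain, 1 of retina described by the submitters as a true control, 5 of control retina and 5 of lesioned retina. The control and lesioned retinas had 1 array each at 2, 3, 5, 7 and 14 days post-lesion. The submitters' design text gives matched animals and at least 8 per condition, without saying how many animals went onto each array, how the lesion was made or whether samples were pooled. These points are not given in the sources used here.

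The deposited values are signal intensities on a linear scale, 1 per probe set, made with the Affymetrix GCOS software per the submitters' processing notes; its version and settings are not given in the sources used here. The deposited intensity of each array had a mean near 500 after leaving out the lowest and highest 2% of probe sets (499.7 or 499.8 on all 12 arrays), so a scaling of each array to a common mean had already been applied. Detection calls were not used here. Each array held 15617 probe sets, of which 115 manufacturer controls were left out, leaving 15502.

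Probe sets were named through the platform annotation provided with the series. It gave 1 gene symbol for 10795 probe sets, several for 135 and none listed for 4572; only probe sets with 1 symbol are named. The gene identifier of 10711 of them was found in a current gene table (assembly GRCz12tu), which changed 1 symbol, and 8793 distinct genes were represented. No reference genome was used here and no coordinates are given.

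Intensities were analysed as log2(signal + 50), where 50 is the 25th percentile of all retina values rounded to 1 significant digit, so fold changes of dim probe sets are understated. Probe sets under the 40th percentile of the mean of the group means were left out of each comparison, which left 9301 tested. Tests were made with limma 3.58.1 (lmFit, and eBayes with an intensity trend) in R 4.3.3 with statmod 1.5.0, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Plots were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. All adjusted p-values in the text come from limma unless another test is named, and all tests are two-sided unless said otherwise.

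There were 5 comparisons. Lesioned and control retinas were compared over the 5 days with the day as a block, so a call is of the mean change over the days, which need not have the same sign on each. Each day's lesioned array was also compared alone with the 6 unlesioned retinas. The trend asked whether the lesion change moved with log2 of the day, in a fit with the day as a block and 3 residual degrees of freedom. Brain was compared with the 6 unlesioned retinas, and the true control retina with the 5 day controls. In the by-day, brain and true control comparisons 1 side has a single array, which was assumed to vary like the retinas it was compared with. Nothing in the sources used here says which arrays came from separate animals, and the 5 days are not replicates of 1 time, so p-values measure only the spread between these arrays, which may in part be technical.

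The pairing of control and lesioned arrays by day was taken from the design text and the day in each title, and was checked in the values. Deviations from the group means of the control and lesioned arrays of a day correlated at 0.880, 0.812, 0.758, 0.816 and 0.900 on days 2, 3, 5, 7 and 14. Every control array correlated best with the lesioned array of its own day, and the reverse was not checked. Within the array groups described in the next paragraph, the correlations were 0.323 to 0.679. The highest Spearman correlation between 2 arrays of a group was 0.973, and no arrays were duplicates.

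Hybridization control probe sets separated the arrays into 2 groups of 6, called array blocks. Block 1 held brain, the true control and the arrays of days 2 and 14, and block 2 held the arrays of days 3, 5 and 7. Both arrays of a day always lay in the same block. A block term was added to the by-day, brain and true control fits as an alternative chosen after the data were seen, as was a fit of the lesion with the GAPDH 5'/3' ratio of each array as a covariate.

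The 24 gene lists were fixed before the data were examined: rod phototransduction, cone phototransduction, Müller glia, regeneration-associated Müller glia, cell cycle and DNA replication, immune cells and microglia, complement and acute phase, immediate early and JAK-STAT response, extracellular matrix and remodelling, axon growth and cytoskeleton, retinal ganglion cells, inner retinal neurons, lens, retinal pigment epithelium and pigment cells, erythrocytes, muscle, brain regional transcription factors and neuropeptides, myelin and oligodendrocytes, protein folding and heat shock, proteasome, cholesterol and isoprenoid synthesis, circadian clock, ribosomal proteins, and the mitochondrial respiratory chain. Lists with at least 5 measured genes, at 1 probe set per gene, were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, which asks whether a list's genes move on balance in 1 direction. That gave 22 lists in the lesion fits and 23 in the brain fit. Camera compares a list with the other genes on these arrays, while fry tests a list against no change and compares it with no other genes. Some genes stand in more than 1 list.

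Genes to be named were also fixed by rule before the data were examined. For the lesion the rule took the 12 largest rises and the 12 largest falls past the threshold with the same direction on all 5 days. For the days it took up to 5 each way with a matched log2 ratio of at least 1 in size, for the trend 6 each way or else the 4 of smallest p, for brain 12 each way, and for the true control 4 each way. Up to 4 members of each list past its test, or with at least 3 called members, were added. Further genes were always named where measured: rho, gfap, pcna, stat3, mmp9, ascl1a, hspd1, mdka, mdkb, apoeb and lgals2a. No probe set was assigned to rho alone, so it is not reported here.

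Other settings tried were pseudocounts of 12.5 and 200, no filter and a filter at the 60th percentile, quantile normalization, median centring, no intensity trend, robust eBayes, an adjusted p threshold of 0.1, fits without the pairing, and leaving out each day or array in turn. Before use, each fit was tested on simulated data of 9301 probe sets with 50 changed at each of several sizes. The lesion fit recovered 64.0% of changes of 0.50 on the log2 scale and 100% of changes of 1.00, with 5.21% false calls. The trend fit recovered 74.0% at 0.50 per doubling of the day, with 2.60% false calls. The day 2 fit recovered 0% at 1.00, 54.0% at 2.00 and 78.0% at 3.00, the brain fit 58.0% and 88.0% at the last 2 sizes, and the true control fit 38.0% and 84.0%. False calls were 2.94%, 8.43% and 4.62% in these 3 fits, so that of brain was above the threshold of 0.05. The simulated noise was independent between probe sets and drawn at each fit's own variance. Genes on real arrays are not independent, so these rates need not hold for the real data. The number of arrays limits the precision of every comparison.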

Results

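Adult zebrafish regrow retinal neurons after injury from Müller glia, the radial glia of the retina, and this series profiled intact and lesioned retina with brain as a reference tissue. Transcript levels were measured as scaled Affymetrix signal intensities on 12 arrays, with 1 brain array, 1 true control retina, and 5 control and 5 lesioned retinas from matched animals at 2, 3, 5, 7 and 14 days post-lesion. Each value is 1 array, so no day or tissue has replicates of its own. Counts of retinas are counts of arrays, and the number of animals on an array is not given in the sources used here. The median signal of an array was 134 to 205.

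The arrays lay in 2 blocks that cut across lesion status. The RNA quality probe sets for GAPDH gave a 5'/3' signal ratio of 0.692 to 0.854 in brain, the true control and days 2 and 14, against 0.103 to 0.245 on days 3, 5 and 7. Mean hybridization control signal was 1419 to 1821 in block 1 and 2612 to 4005 in block 2, and the highest signal of an array was 29844 to 34084 against 56928 to 90586. Spearman correlations of retina arrays were 0.967 to 0.982 within block 1, 0.934 to 0.965 within block 2 and 0.868 to 0.911 across blocks. Brain correlated at 0.854 to 0.864 with the retinas of block 1 and at 0.788 to 0.820 with those of block 2. The GAPDH ratio was also lower in the lesioned than in the control array on 5 of 5 days, by a mean log2 difference of -0.27 ± 0.23 (SD, n = 5; exact sign-flip permutation p = 0.0625, the smallest possible). The difference was -0.03, -0.62, -0.35, -0.25 and -0.08 on days 2, 3, 5, 7 and 14.

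**Figure D1:**
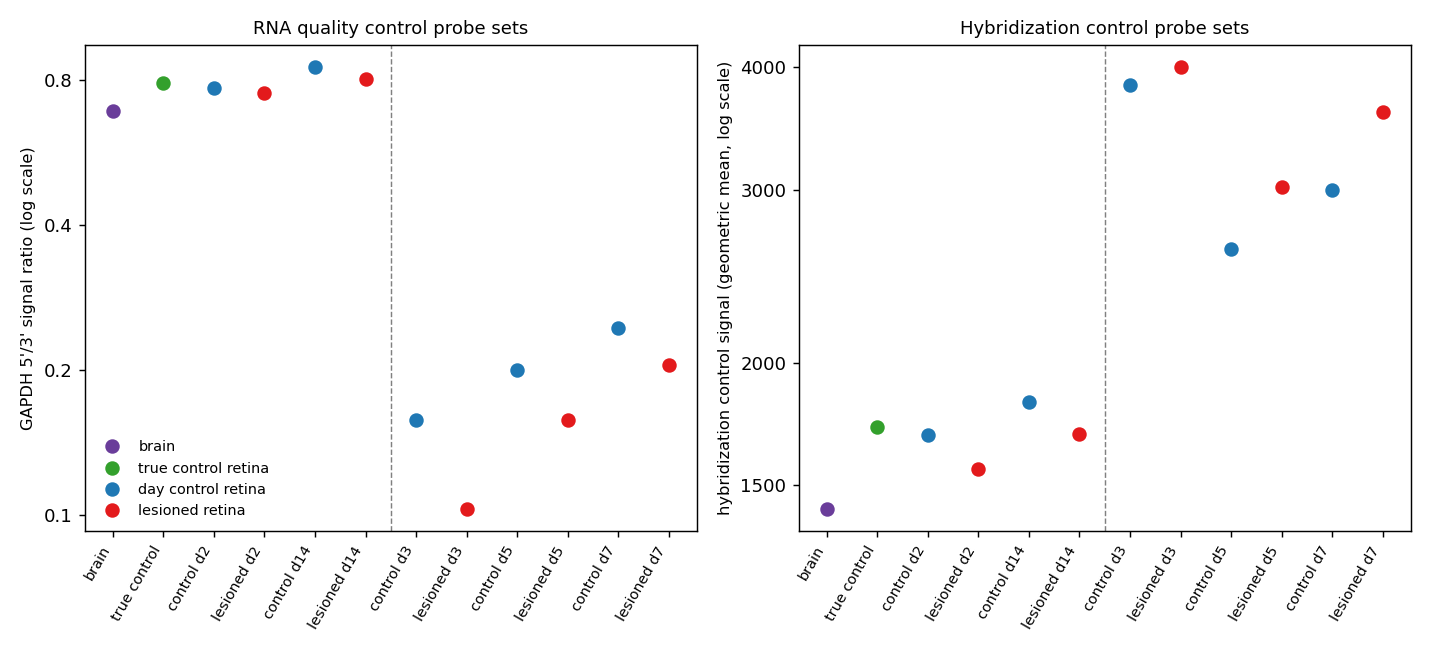
Each point is 1 of the 12 arrays, in order of array block and day, with the GAPDH 5'/3' signal ratio on a log axis on the left and the mean hybridization control signal on a log axis on the right. The dashed line parts block 1, with GAPDH ratios of 0.692 to 0.854, from block 2, with 0.103 to 0.245.

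Genes that rose in lesioned retinas against control retinas of the same day included the matrix protease mmp9, the complement gene c7b, the growth cone gene gap43 and the cyclin ccnd1, and the photoreceptor gene rp1l1a was among those that fell. The largest fitted rise was in mmp9, a secreted protease that degrades extracellular matrix (log2 change 3.45 ± 0.24 SE, n = 5 pairs; limma adjusted p = 6.19e-06). Its signal was 31.4 ± 22.5 (SD, n = 5) in control and 990.4 ± 569 in lesioned retinas. The control mean lay under the lower quartile of every array (34.6 to 80), so the added 50 sets the size of that change. The ranking of rises and falls covers called genes with 1 symbol and the same direction on all 5 days. On the same log2(signal + 50) scale mmp9 was followed by c7b, a component of the terminal complement pathway, at 5.11-fold. Next were mvp, the major vault protein, at 4.38-fold, and socs3a, a feedback inhibitor of cytokine signalling through STAT3, at 3.80-fold. Outside the ranking, a probe set without a single gene symbol had matched log2 ratios of 5.08, 4.06, 1.68, 2.56 and 0.59 on days 2, 3, 5, 7 and 14. The largest fall was in rp1l1a, a gene of the photoreceptor outer segment axoneme, which fell 1.80-fold (log2 change -0.85 ± 0.15 SE; limma adjusted p = 0.00450).

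In all, 381 of 9301 probe sets changed, 331 up and 50 down, and 1684 had an unadjusted p under 0.05. They covered 268 genes that rose and 32 that fell. Of the 381, 298 risen and 46 fallen probe sets had the same direction on all 5 days. At least a 2-fold change was seen for 68 risen probe sets and for 0 of the 50 that fell in limma's test. Median ratios of the risen set were 0.65, 0.80, 0.84, 0.73 and 0.31 on the log2 scale on days 2, 3, 5, 7 and 14, and those of the fallen set were -0.60, -0.75, -0.47, -0.41 and -0.26. Ratios of different days correlated across probe sets, which are not independent, at Pearson r of 0.113 to 0.465.

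Among the other 12 leading rises were atf3 and jun, stress-induced transcription factors, at log2 1.78 ± 0.20 and 1.54 ± 0.21. The tubulin genes tuba5 and tuba1b rose by 1.78 ± 0.24 and 1.47 ± 0.16. Also among them were grna.1, a granulin gene, at 1.67 ± 0.25, the interferon-induced ifi27.1 at 1.51 ± 0.20, and the galectin pathway genes lgals3bp.1 and lgals2a at 1.68 ± 0.21 and 1.49 ± 0.14. Adjusted p was between 8.98e-05 (lgals2a) and 0.00304 (socs3a) for the leading rises after mmp9. All 12 stayed past the threshold when any single day was left out. The leading falls were smaller: zgc:195245 (-0.84 ± 0.15), letm1, a mitochondrial inner membrane protein (-0.66 ± 0.12), desi1a (-0.64 ± 0.16), ppp1r3c2b, a regulator of glycogen metabolism (-0.64 ± 0.10), and cry1b, a cryptochrome of the circadian clock (-0.59 ± 0.10). Others were arhgap29a (-0.57 ± 0.12), fthl30, a ferritin heavy chain gene (-0.56 ± 0.11), id2b, an inhibitor of DNA binding (-0.56 ± 0.12), usp21 (-0.54 ± 0.13), pank2, a kinase of coenzyme A synthesis (-0.54 ± 0.11), and uckl1a (-0.52 ± 0.11).

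**Figure D2:**
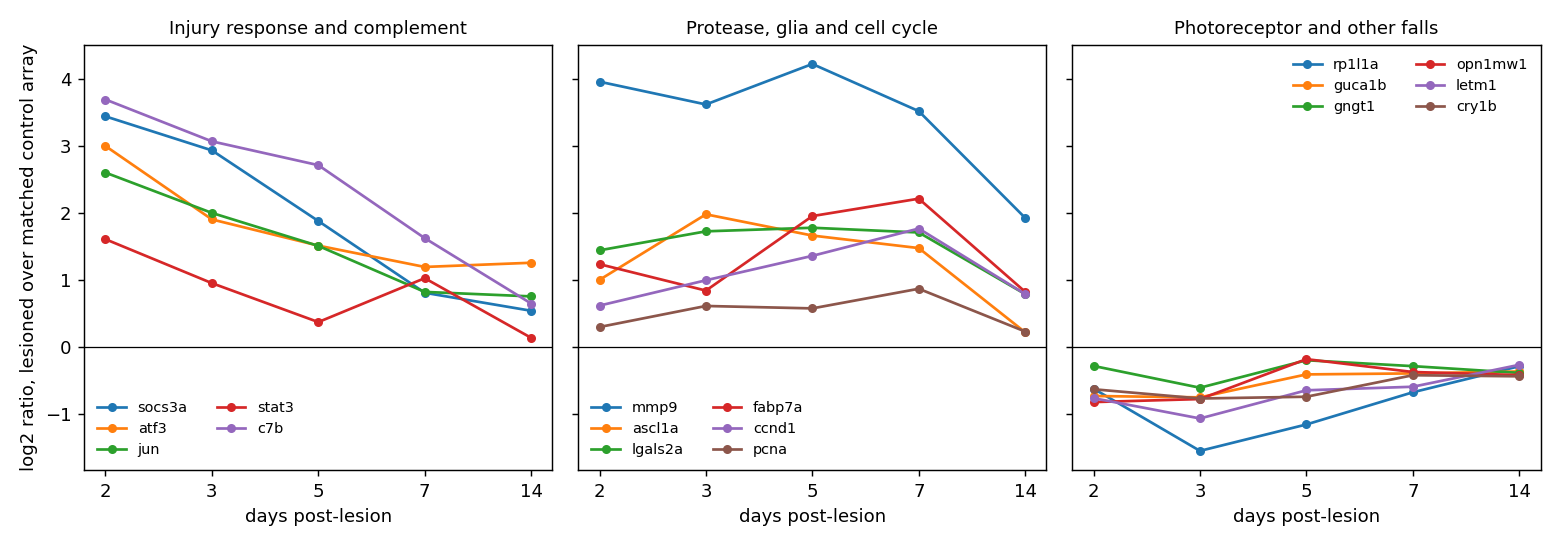
Each point is the log2 ratio of the lesioned over the control array of the same day (1 array each), joined by gene, against days post-lesion on an evenly spaced axis. The ratio of mmp9 is 3.96 on day 2 and 1.93 on day 14, while that of rp1l1a is lowest on day 3, at -1.54.

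Immune genes had the highest median of the 22 lists tested. Of 25 measured immune cell and microglia genes 17 rose and 0 fell, with 20 up and 1 down when adjusted over the list alone, and a list median of 0.86. Examples are lgals3bp.1, grna.1, grna (1.39 ± 0.14), which encodes a granulin, and laptm5 (1.18 ± 0.20), a lysosomal membrane protein of blood cells. The list shifted up in camera (adjusted p = 8.04e-20), a call lost at adjusted p = 0.127 with an estimated correlation. The erythrocyte list moved with it, at a median of 0.34. Extracellular matrix and remodelling had 13 of 33 genes up, 24 adjusted over the list alone. Among these were mmp9, the simple epithelial keratins krt18a.1 (1.35 ± 0.17) and krt8 (1.23 ± 0.14), and col1a1a (1.11 ± 0.20), the collagen I alpha chain. Its median was 0.45, with a camera adjusted p of 3.69e-16 and adjusted p = 0.127 with an estimated correlation. Complement and acute phase genes, where c7b belongs, had only 4 measured members and were not tested as a list.

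Axon growth and cytoskeleton genes rose in 10 of 22 cases, 11 adjusted over the list alone, with a median of 0.28 (camera adjusted p = 1.02e-10; adjusted p = 0.0887 with an estimated correlation). They included gap43, a growth cone protein, at 1.44 ± 0.16, besides atf3, jun and tuba1b. Immediate early and JAK-STAT genes rose in 12 of 37 cases, with 17 up and 1 down adjusted over the list alone and a median of 0.31. They were led by socs3a, atf3, jun and socs3b (1.43 ± 0.19), the paralog of socs3a. Camera gave these genes an adjusted p of 8.89e-08, and adjusted p = 0.242 with an estimated correlation. The transcription factor stat3 rose by 0.82 ± 0.17 (adjusted p = 0.0117).

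Of 20 Müller glia genes 4 rose, 8 adjusted over the list alone. The 4 were fabp7a, a brain fatty acid binding protein (1.42 ± 0.18), icn, an S100 family gene (adjusted p = 0.000290), the intermediate filament gene vim (0.69 ± 0.11) and apoeb, an apolipoprotein E gene (0.46 ± 0.11). The list median was 0.22, with a camera adjusted p of 0.00423 and adjusted p = 0.225 with an estimated correlation. The glial filament gene gfap did not pass (0.35 ± 0.12, adjusted p = 0.117). Regeneration-associated Müller glia genes rose in 9 of 28 cases, with 12 up and 1 down adjusted over the list alone and a median of 0.20 (camera adjusted p = 7.55e-06; adjusted p = 0.127 with an estimated correlation). They included mmp9, socs3a, socs3b, lgals2a and ascl1a, a proneural transcription factor needed for retinal regeneration (1.27 ± 0.20, adjusted p = 0.00198). The heat shock chaperonin hspd1 (0.37 ± 0.12, adjusted p = 0.115), the midkine genes mdka (-0.31 ± 0.09, adjusted p = 0.0766) and mdkb (-0.09 ± 0.10, adjusted p = 0.707) did not pass.

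Cell cycle and DNA replication genes rose in 12 of 39 cases, 19 adjusted over the list alone, with a median of 0.32 (camera adjusted p = 2.70e-10; adjusted p = 0.242 with an estimated correlation). Among them were the G1 cyclin ccnd1 (1.11 ± 0.15), the chromatin factor uhrf1 (0.86 ± 0.16), the replicative helicase subunit mcm2 (0.83 ± 0.18), the condensin subunit smc4 (0.82 ± 0.21) and pcna, the replication clamp (0.52 ± 0.11, adjusted p = 0.0128). The median of the list by day was 0.16, 0.37, 0.36, 0.54 and 0.12 on days 2, 3, 5, 7 and 14.

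Photoreceptor lists moved the other way. Rod phototransduction genes fell in 2 of 15 cases, 11 adjusted over the list alone, with a median of -0.33 (camera adjusted p = 3.48e-08; adjusted p = 0.239 with an estimated correlation). The called genes were guca1b, a guanylate cyclase activator (-0.52 ± 0.10), and gngt1, the rod transducin gamma subunit (-0.35 ± 0.09, adjusted p = 0.0408). Of 26 cone genes 1 fell, over all genes and adjusted over the list alone: opn1mw1, a green-sensitive cone opsin (-0.51 ± 0.11, adjusted p = 0.0133). The cone median was -0.08, with a camera adjusted p of 0.0103 and adjusted p = 0.302 with an estimated correlation. Inner retinal neuron genes had 0 of 22 called by limma, also when adjusted over the list alone, although their median of -0.12 passed camera (adjusted p = 0.000763; adjusted p = 0.127 with an estimated correlation) and fry. Their smallest p-values belonged to the connexins gja9a (-0.50 ± 0.16, adjusted p = 0.102) and gja10b (-0.30 ± 0.13), the transcription factor bhlhe22 (-0.27 ± 0.11) and the bipolar cell factor vsx1 (-0.24 ± 0.10). Retinal ganglion cell genes rose in 2 of 15 cases, 4 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.151).

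Ribosomal protein genes rose in 16 of 79 cases, with 57 up and 1 down adjusted over the list alone and a median of 0.33. Examples are rplp2b (0.89 ± 0.16), rpl27a (0.67 ± 0.17), rps12 (0.67 ± 0.11) and rps27l (0.55 ± 0.12). Camera gave an adjusted p of 8.04e-20, and adjusted p = 0.245 with an estimated correlation. The list median was -0.07 on day 14 against 0.20 to 0.60 on the earlier days. Protein folding and heat shock genes rose in 1 of 27 cases, hspb1, a small heat shock protein (0.81 ± 0.14), and in 7 adjusted over the list alone. Their median was 0.20 (camera adjusted p = 0.000117; adjusted p = 0.302 with an estimated correlation). Proteasome genes had 1 riser of 32 both ways, psmb1 (0.47 ± 0.11), a median of 0.12 and a camera adjusted p of 0.000712 (adjusted p = 0.245 with an estimated correlation). The mitochondrial respiratory chain had 0 of 82 called by limma, also adjusted over the list alone, with a median of -0.06 (camera adjusted p = 0.00711; adjusted p = 0.404 with an estimated correlation). Its smallest p-values belonged to cox6b1 (0.30 ± 0.12), ndufs1 (-0.24 ± 0.09), ndufs7 (-0.22 ± 0.09) and atp5f1d (-0.24 ± 0.10), none past the threshold. Cholesterol synthesis genes had 0 of 9 called by limma and a median of -0.18 (camera adjusted p = 0.0199; adjusted p = 0.302 with an estimated correlation). None passed adjusted over the list alone either. The enzymes msmo1 (-0.32 ± 0.11), fdps (-0.28 ± 0.12), dhcr7 (-0.23 ± 0.11) and fdft1 (-0.22 ± 0.12) had the smallest p-values. Another probe set of fdps went the other way. In the circadian clock list cry1b was the 1 of 22 genes that fell, with a median of -0.05 (camera adjusted p = 0.0330; adjusted p = 0.225 with an estimated correlation).

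Markers of other cell types were examined too. Erythrocyte genes had 0 of 7 called by limma but 3 up adjusted over the list alone, with a median of 0.34 (camera adjusted p = 0.0125; adjusted p = 0.245 with an estimated correlation). The alpha globin hbaa1 was at 1.01 ± 0.32 (adjusted p = 0.0902), with ratios of 1.93, 2.53, 0.78, 0.60 and -0.78 on days 2, 3, 5, 7 and 14. The beta globin hbba2 was at 0.69 ± 0.31, the heme synthesis enzyme alas2 at 0.39 ± 0.13 and nt5c2l1 at 0.34 ± 0.13, none past the threshold. Pigment epithelium and pigment cell genes rose in 1 of 6 cases, pmelb, a melanosome protein (0.66 ± 0.14), with a median of 0.20 (camera adjusted p = 0.0417; adjusted p = 0.302 with an estimated correlation). Muscle (camera adjusted p = 0.725), myelin (0.205) and brain regional genes (0.0564) did not pass and had 0 calls by limma, though 2 myelin genes were up adjusted over the list alone. The lens list had 1 measured gene. Of the 22 lists, 18 passed camera, 0 with an estimated correlation, where 5 had an unadjusted p under 0.05. In fry 6 passed: Müller glia, regeneration-associated Müller glia, immune, matrix and axon genes upward and inner retinal neurons downward.

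**Figure D3:**
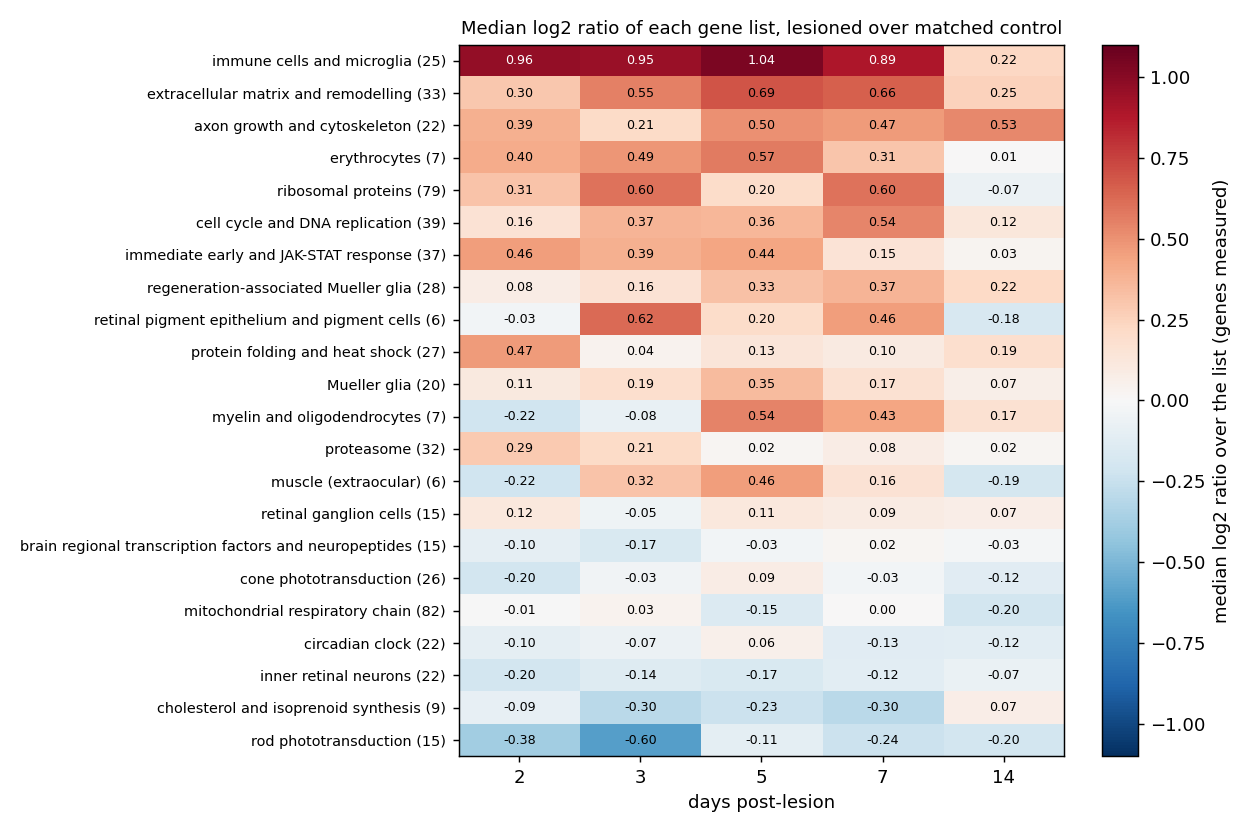
Each cell is the median log2 ratio of a gene list on 1 day, lesioned over control array, with the number of measured genes in parentheses and colour from blue (lower) to red (higher). The immune list stays between 0.89 and 1.04 through day 7 and is at 0.22 on day 14.

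The count of changed probe sets rested on the pairing by day: without it limma called 0, with 351 at an unadjusted p under 0.05. Left-out days moved the count from 381 to 239 (day 3), 195 (day 5), 165 (day 7) and 573 (day 14). The pairs of block 2 alone gave 494 and those of block 1 alone 0 by limma (784 at an unadjusted p under 0.05). With the GAPDH ratio as a covariate 10 of the 381 were called, among them mmp9, mvp, atf3, lgals2a and gap43. The median of the risen probe sets was then 0.54 in place of 0.67, with 100% of the same sign, and that of the fallen -0.37 in place of -0.50, with 98%. Of the 52 named genes that were called, 20 lost their call when 1 day was left out, with the highest adjusted p at 0.193. They were desi1a, arhgap29a, fthl30, id2b, usp21, pank2, uckl1a, gngt1, opn1mw1, apoeb, mcm2, smc4, col1a1a, pmelb, psmb1, rplp2b, rpl27a, rps27l, pcna and stat3.

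Against the 6 unlesioned retinas pooled, day 3 had the most probe sets at an unadjusted p under 0.05 in limma. Calls at the adjusted threshold were most numerous on day 2. On that day 6 probe sets passed, all up, each with a limma adjusted p of 0.0203. They were c7b (log2 4.25 ± 0.44), mmp9 (3.69 ± 0.40), esm1, an endothelial proteoglycan gene (3.42 ± 0.37), atf3 (10.5-fold, 3.39 ± 0.36), jun (7.67-fold, 2.94 ± 0.31) and gap43 (2.31 ± 0.24). The gene gap43 lies outside the naming rule and was named after its value was seen. The matched ratio of esm1 was 3.76 on day 2 and 0.74, 0.66, 0.11 and 0.02 on days 3, 5, 7 and 14. On day 5 only mmp9 passed (4.41 ± 0.40, adjusted p = 0.0320).

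Limma called 0 probe sets on days 3, 7 and 14, where 758, 397 and 111 had an unadjusted p under 0.05. With the array block as a term, days 2, 3, 5, 7 and 14 had 16, 8, 8, 5 and 0 calls, the last with 238 at an unadjusted p under 0.05. In that fit mvp (3.39 ± 0.25), hsp70.3, an inducible heat shock protein (2.03 ± 0.27), flna, an actin crosslinker (2.16 ± 0.24), irf1b, an interferon regulatory factor (1.89 ± 0.28), and the peptide YY gene pyya (1.94 ± 0.22) joined on day 2. On day 3 ascl1a (2.13 ± 0.24), socs3b (adjusted p = 0.0103) and ubap2b (1.53 ± 0.21) were up and gnat1, the rod transducin alpha subunit, was down (-1.36 ± 0.19, adjusted p = 0.0477). On day 5 kpna2, a nuclear import receptor (2.34 ± 0.29), and igldcp (2.54 ± 0.30) were up and oxct1a, an enzyme of ketone use, was down (-2.12 ± 0.28, adjusted p = 0.0436). On day 7 rrm2l (2.34 ± 0.24), kpna2 (2.49 ± 0.29), ccnd1 (1.94 ± 0.25) and grna.1 (2.87 ± 0.33) were up with mmp9. These genes too were named after their values were seen. Without any 1 of the 6 unlesioned arrays limma called 0 on days 2 and 5, with 199 to 333 and 284 to 500 probe sets at an unadjusted p under 0.05. Whether days differed from each other was tested only through the trend.

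The lesion change shrank with time for a small set of probe sets. Of 9301 probe sets 10 moved with log2 of the day, all downward, and 329 had an unadjusted p under 0.05. The steepest slope per doubling of the day, -1.55 (SE 0.19, limma adjusted p = 0.00173), belonged to a probe set without a single gene symbol. Among the named genes, socs3a fell by 1.13 per doubling of the day (SE 0.13, adjusted p = 0.00151) and c7b by 1.09 (SE 0.12). The alpha globin hbaa1 also sloped down (adjusted p = 0.00561). The immediate early factor fosab fell by 0.87 (SE 0.15) per doubling, tuba5 by 0.77 (SE 0.14) and jun by 0.69 (SE 0.12). The ratio of socs3a was 3.44, 2.94, 1.88, 0.81 and 0.55 on days 2, 3, 5, 7 and 14.

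Rises with the day did not pass. The smallest p-values were those of cd59a, a complement regulator (0.56 ± 0.15, adjusted p = 0.436), the invariant chain gene cd74a (0.73 ± 0.19, adjusted p = 0.436), tubb5 (0.55 ± 0.16) and usp21 (0.35 ± 0.11). Immediate early and JAK-STAT genes had 3 of 37 members called, all downward and 11 adjusted over the list alone, with a median slope of -0.17 (camera adjusted p = 3.59e-13; adjusted p = 0.404 with an estimated correlation). Immune genes had a median slope of -0.23 and 0 of 25 called by limma, with 1 up and 8 down adjusted over the list alone (camera adjusted p = 1.07e-06; adjusted p = 0.404 with an estimated correlation). Examples are cd63 (-0.44 ± 0.12, adjusted p = 0.436), ccl19a.1 (-0.45 ± 0.12) and cxcl12a (-0.40 ± 0.11), none past the threshold. Another probe set of cxcl12a sloped the other way. Ribosomal protein genes had a median slope of -0.14, with rplp2b at -0.39 ± 0.13, rpl27a at -0.36 ± 0.14, rpl38 at -0.32 ± 0.12 and rpl29 at -0.30 ± 0.12, and adjusted p = 0.505 with an estimated correlation. The slope of heat shock genes was -0.11, with hsp70.3 at -0.63 ± 0.19, hspb1 at -0.37 ± 0.11, pdia3 at -0.29 ± 0.11 and hspe1 at -0.26 ± 0.11, and adjusted p = 0.505 with an estimated correlation. Mitochondrial (-0.08), proteasome (-0.06), erythrocyte (-0.10) and pigment epithelium (-0.18) lists also passed camera downward, each at adjusted p = 0.404 with an estimated correlation. The only called member of these 6 lists was hbaa1, and adjusted over the lists alone 2 erythrocyte genes and 1 pigment gene passed.

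Upward slopes passed camera for rod (0.12), myelin (0.17) and ganglion cell genes (0.05), with 0 members called by limma and adjusted p = 0.404 with an estimated correlation for each. Adjusted over the lists alone 1 myelin gene passed upward. Slopes in the rod list included nr2e3, a rod transcription factor (0.31 ± 0.13), prph2b, a disc rim protein (0.28 ± 0.13), and the channel subunit cnga1a (0.22 ± 0.10). In the ganglion cell list prph (0.34 ± 0.13), thy1 (0.29 ± 0.13) and pou4f2 (0.23 ± 0.12) sloped up and gap43 down (-0.33 ± 0.14). In the myelin list olig2 was at 0.25 ± 0.14, cldnk at 0.17 ± 0.13 and mbpa at 0.17 ± 0.12. None of these genes passed. The other 11 of the 22 lists, cone, Müller glia, regeneration, cell cycle, matrix, axon, inner retinal, muscle, brain, cholesterol and circadian genes, did not pass camera. In the regeneration list the median was 0.02 while the mean and the test pointed down. The count of 10 was 5 without day 7, 6 without day 5 and 1 without day 14, and 0 when days 2, 3 and 5 were set against days 7 and 14 (329 at an unadjusted p under 0.05 by limma). Without day 14, camera passed 4 of the 11 lists in the same direction, the immediate early, heat shock, rod and myelin lists. Cell cycle, matrix, cone, Müller glia and muscle genes then passed upward as well. With an estimated correlation 0 lists passed without day 14, also at an unadjusted p under 0.05, and the lowest was adjusted p = 0.489.

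Photoreceptor genes were lower in brain than in unlesioned retina, with 24 of 25 cone and 13 of 15 rod genes called. Among genes higher in brain, the first by fitted change was epd, ependymin, a glycoprotein of the brain's extracellular fluid (log2 8.87 ± 0.28, 1 brain array against 6 retinas; limma adjusted p = 2.15e-06). Its signal was 27559 in brain and 9.13 ± 5.08 (SD, n = 6) in retina. Among lower genes the first was gngt2b, the cone transducin gamma subunit (-8.70 ± 0.27, adjusted p = 2.15e-06), where the signal was 12 in brain and 26041 ± 3810 in retina. Both low signals lay under the lower quartile of every array, so the added 50 sets the size of these changes, and the order of the leading genes holds only on the log2(signal + 50) scale. Of 9301 probe sets 1073 differed, 633 higher and 440 lower in brain, with 2296 at an unadjusted p under 0.05. With the array block as a term 2261 differed, 1307 higher and 954 lower. Within block 1 alone 2666 did. The median over all tested probe sets was 0.15.

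Higher in brain were also s100b, a calcium-binding protein of glia (6.31 ± 0.32), cyp19a1b, the brain aromatase (5.33 ± 0.36), the glutamate receptor subunit grik6 (5.31 ± 0.31) and fxyd3, a regulator of the sodium pump (5.27 ± 0.47). The hormone genes pmchl (5.21 ± 0.48) and oxt (5.12 ± 0.32), the hindbrain and cerebellar factor zic1 (4.79 ± 0.25), the calcium buffer pvalb7 (4.65 ± 0.62) and aldoca, an aldolase of cerebellar neurons (4.47 ± 0.43), followed. The last of the 12 were rbp4, a retinol carrier (4.35 ± 0.42), and ggctb (4.26 ± 0.52). Lower in brain were gatd3l (-8.66 ± 0.34), the cone phosphodiesterase genes pde6hb (-8.27 ± 0.21) and pde6c (-7.16 ± 0.73), the opsins opn1sw1 (-7.56 ± 0.43), opn1mw2 (-7.48 ± 0.34) and opn1mw1 (-6.94 ± 0.29), and the cyclase activators guca1c (-7.24 ± 0.76) and guca1b (-6.94 ± 0.26). The remaining leading deficits were zgc:193593 (-7.19 ± 0.48), the cone transducin subunit gnb3b (-6.99 ± 0.25) and the phosducin gene pdcb (-6.84 ± 0.36).

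**Figure D4:**
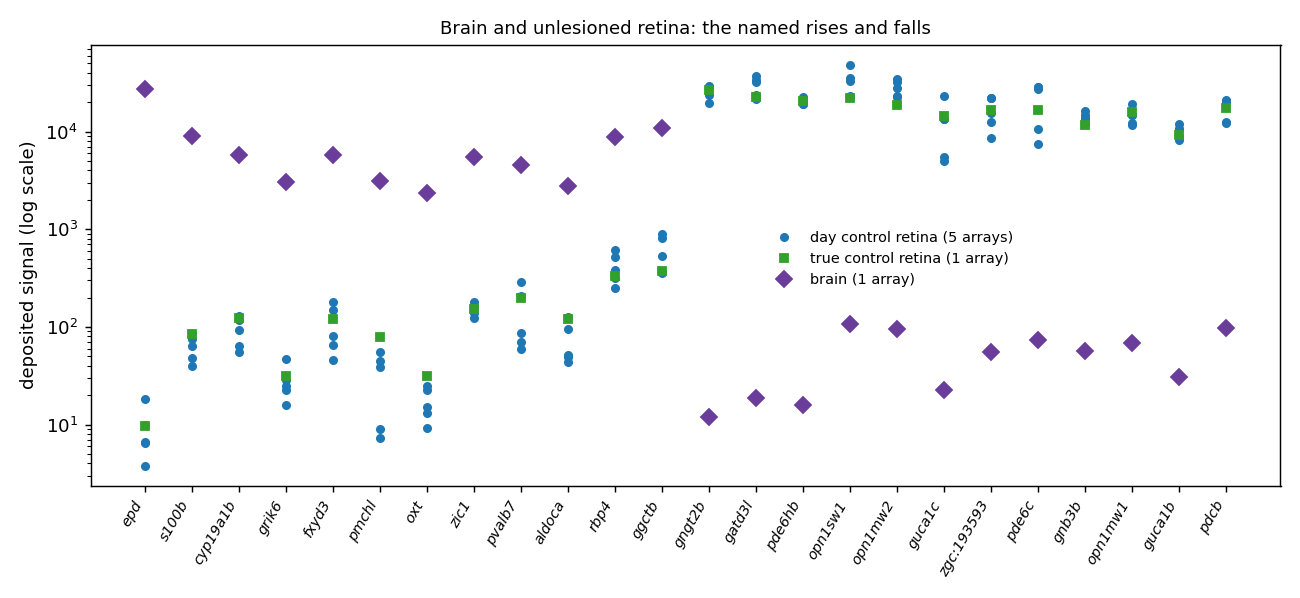
Points are deposited signals on a log axis of the 12 genes first by fitted change each way in brain, in the brain array, the true control retina and the 5 day control retinas. The brain signal is 27559 for epd and 12 for gngt2b, outside the range of the 6 retinas for all 24 genes.

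Cone phototransduction genes were lower in brain in 24 of 25 cases, 25 adjusted over the list alone, with a median of -6.42 (camera adjusted p = 2.47e-38; adjusted p = 0.000589 with an estimated correlation). Rod genes were lower in 13 of 15, 14 adjusted over the list alone, with a median of -5.99 (camera adjusted p = 1.70e-23; adjusted p = 0.00167 with an estimated correlation). Examples are pdca (-6.80 ± 0.45) and rom1b (-6.61 ± 0.20). These were the 2 lists that held with an estimated correlation. Brain regional transcription factors and neuropeptides were higher in 29 of 39 cases and lower in 1, with 34 and 1 adjusted over the list alone and a median of 2.39; zic5 was at 4.12 ± 0.41. Their camera adjusted p was 4.18e-20, and adjusted p = 0.0638 with an estimated correlation, or 0.0158 with the array block as a term.

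Myelin genes were higher in 3 of 8 cases (7 adjusted over the list alone and 7 with the array block), among them olig2 (1.99 ± 0.26), mbpa, a myelin basic protein gene (1.72 ± 0.41), and gpm6ab (1.25 ± 0.25). Muscle genes were higher in 8 of 13 cases, with 10 up and 1 down adjusted over the list alone. Among them were the creatine kinases ckma (3.25 ± 0.42) and ckmb (3.24 ± 0.37), the calcium pump atp2a1 (2.69 ± 0.58) and the troponin tnnt3b (2.69 ± 0.44). Axon growth genes were higher in 6 of 22 cases (8 adjusted over the list alone and 10 with the array block). The growth cone genes gap43 (2.97 ± 0.25) and stmn2a (2.72 ± 0.35), marcksb (adjusted p = 0.00557) and tmsb (2.17 ± 0.53) were among them. These 3 lists passed camera (adjusted p = 0.000195, 0.000113 and 0.000135), each at adjusted p = 0.0638 with an estimated correlation. Immune genes were higher in 7 of 19 cases, 11 adjusted over the list alone and 12 with the array block. Examples are b2m, the light chain of MHC class I (2.39 ± 0.63), cd74b (2.27 ± 0.51), cd63 (2.26 ± 0.57) and ccl19a.1 (2.09 ± 0.36). Camera gave the list an adjusted p of 4.04e-05, and adjusted p = 0.251 with an estimated correlation. Matrix genes were higher in 3 of 28 cases, 4 adjusted over the list alone: dcn, the proteoglycan decorin (3.36 ± 0.50), s100v2 (2.05 ± 0.30) and mmp2 (1.49 ± 0.33). The matrix list had a camera adjusted p of 0.0220 and adjusted p = 0.422 with an estimated correlation. Complement and acute phase genes had 2 of 7 higher and 1 lower, or 3 and 1 adjusted over the list alone. Higher were cp, ceruloplasmin (4.22 ± 0.40), and c4 (1.90 ± 0.34), and lower was ambp (-3.42 ± 0.89). Their camera adjusted p was 0.0298, and adjusted p = 0.422 with an estimated correlation.

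Inner retinal neuron genes were lower in brain in 7 and higher in 2 of 21 cases, with 11 and 4 adjusted over the list alone (camera adjusted p = 0.00238; adjusted p = 0.152 with an estimated correlation). The bipolar cell genes vsx1 (-4.60 ± 0.44) and cabp5b (-3.21 ± 0.34) were lower, and the parvalbumins pvalb7 and pvalb6 (2.24 ± 0.40) higher. Circadian genes were lower in 4 of 22 cases, 6 adjusted over the list alone. They were led by aanat2 (-5.79 ± 0.82) and aanat1 (-3.25 ± 0.53), enzymes of melatonin synthesis, with bmal1b (-1.56 ± 0.40) and rorab (-1.37 ± 0.34). Camera gave an adjusted p of 0.00524 for clock genes, and adjusted p = 0.0638 with an estimated correlation. Pigment epithelium genes were lower in 2 of 6 cases, 4 adjusted over the list alone, the retinol transporter stra6 (-3.42 ± 0.73) and rgrb (-3.34 ± 0.84). Camera gave them an adjusted p of 0.0101, and adjusted p = 0.251 with an estimated correlation. Ganglion cell genes were higher in 4 of 15 and lower in 1, or 7 and 2 adjusted over the list alone: elavl4 (2.03 ± 0.34) was higher and inaa, an intermediate filament gene (-3.88 ± 0.28), was lower. The ganglion cell list passed camera, but neither with an estimated correlation nor with the array block as a term. Immediate early genes were lower in 3 of 35 cases under either adjustment, the phosphatases dusp1 (-3.68 ± 0.36) and dusp6 (-1.80 ± 0.22) and ier5 (-1.73 ± 0.42). That list had a camera adjusted p of 0.0252, and adjusted p = 0.387 with an estimated correlation.

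The ribosomal list passed camera upward (adjusted p = 0.0472; adjusted p = 0.749 with an estimated correlation) with 1 gene higher, rps27l (1.11 ± 0.27), and 1 lower of 79, and 0 either way by limma adjusted over the list alone. The lower one, rps6ka3a (-1.63 ± 0.43), encodes a ribosomal protein kinase caught by the list's symbol pattern. Müller glia genes were mixed, with a median of 0.84 over 22 genes, and again 0.84 with the array block as a term. Higher were s100b and the connexin gja1b (2.99 ± 0.34), and lower were rlbp1a, a retinaldehyde carrier (-5.33 ± 0.26), and ca2 (-2.18 ± 0.51). The list did not pass camera (adjusted p = 0.170). The regeneration-associated list of 27 genes did not pass camera. Its median was -0.16, or 0.21 with the array block as a term, while its mean was -0.29 or -0.37. The galectin lgals2a (2.69 ± 0.57) was higher. The eye field transcription factors pax6a (-3.34 ± 0.33), pax6b (-2.73 ± 0.73) and rx2 (-2.30 ± 0.35) were lower. Cell cycle (camera adjusted p = 0.625), erythrocyte (0.785), heat shock (0.927), proteasome (0.628), cholesterol (0.990) and mitochondrial lists (0.785) did not pass, with 1, 1, 1, 0, 0 and 2 called genes by limma. The median and the test pointed opposite ways for the heat shock, cholesterol and mitochondrial lists. Tissue differences could be called in limma only against the spread of the retina arrays, since there was 1 brain array.

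The true control retina was set against the day controls to ask whether they differed. The labels do not say what sets it apart from them. Limma called 0 of 9301 probe sets, with 68 at an unadjusted p under 0.05. With the array block as a term 4 probe sets were lower in the true control, with 312 at an unadjusted p under 0.05, and within block 1 alone, where 1 array met 2 controls with 1 residual degree of freedom, 12 were called higher and 26 lower. The 4 were both probe sets of tph1a, the rate-limiting enzyme of serotonin synthesis (-2.85 ± 0.33 and -2.75 ± 0.31), fsta, the activin inhibitor follistatin (-2.79 ± 0.29), and uacab (-2.75 ± 0.29), each at adjusted p = 0.0189.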

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

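The tests of RNA quality and of a lower share of neurons (each replaced once after its value was known), of the array blocks, of probe set counts under other splits and of list slopes without day 14 at an estimated correlation were chosen only after the result was seen, as was the margin of 1 SE in the test of blood, whose slope and bound were fixed beforehand like the test of list counts under other splits.

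A single array stood apart from the other 4 of its group for 7 of the named genes, where the gap to the nearest array exceeded a share of 0.71 of the whole range (Dixon's 95% criterion). Chance alone gives about 1 in 20 groups, or 7.5 of the 150 groups examined. Among control retinas, tuba1b was low on day 2 (share 0.741), and fdps (0.766) and atp5f1d (0.775) were high on day 14. Among lesioned retinas, atf3 was high on day 2 (0.758), ifi27.1 high on day 5 (0.867), zgc:195245 low on day 3 (0.741) and vsx1 high on day 14 (0.799).

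The lesion change differed between days, by the test of the slope on log2 of the day, for 6 named genes. Per doubling of the day the slope was -1.13 for socs3a, -1.098 for hbaa1, -1.09 for c7b, -0.87 for fosab, -0.77 for tuba5 and -0.69 for jun. Of the 10 called probe sets, 5 were also called without day 2, 8 without day 3, 6 without day 5, 5 without day 7 and 1 without day 14. Gene lists past camera had median slopes of -0.23 (immune), -0.18 (pigment epithelium), -0.17 (immediate early and JAK-STAT), -0.14 (ribosomal), -0.11 (heat shock), -0.10 (erythrocyte), -0.0767 (mitochondrial) and -0.0591 (proteasome). Median slopes were 0.17 for myelin, 0.12 for rod and 0.0485 for ganglion cell genes. All 11 calls were lost with an estimated correlation, at adjusted p = 0.404 or 0.505. Without day 14, 4 of these 11 lists passed: immediate early and heat shock genes downward, rod and myelin genes upward, and with an estimated correlation 0 did, also at an unadjusted p under 0.05.

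The first pattern weighed was the change of 381 probe sets while the GAPDH 5'/3' ratio was lower in every lesioned array. With that ratio as a covariate the 331 risen probe sets went from a median of 0.67 (median SE 0.13) to 0.54 (SE 0.20) and the 50 fallen ones from -0.50 (SE 0.11) to -0.37 (SE 0.17), and 10 and 0 were called. The ratio correlated with the lesion within days at -0.789 and left 3 residual degrees of freedom. The estimates shrank and the SEs grew, and how much of the loss of calls came from each was not tested. Days 2 and 14 had GAPDH gaps of 8.49% and 20.3% of the mean on days 3, 5 and 7, and there the 386 risen and 72 fallen probe sets called from those 3 days alone (of 422 and 72, those within the 9301 tested) had 49.4% and 25.4% of their change. A test on day 2 alone was used first and gave 63.1% and 51.0%, above its bound of 50%, but it rested on 1 pair, and day 14 gave 29.0% and 5.32%. With both days the shares lie between the bounds of 25% and 50%. The 331 risen and 50 fallen probe sets also changed least on day 14 (medians 0.31 and -0.26). A low share on day 14 could thus come from a change that fades as well as from RNA quality. Shorter or degraded RNA therefore cannot be told apart from the lesion as a cause of either set. The risen median of 0.38 on days 2 and 14 lay above the central range of 10000 random lists matched on signal (-0.02 to 0.02).

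Of 100 splits of the 10 arrays into 5 and 5, only 1, the real one, called as many as 381 probe sets, and the highest other count was 218, but splits that put both arrays of a day on 1 side lose that pair, so this comparison is not read as excluding chance. The arrays are paired by day, and the 16 splits that part every pair are the closer comparison, but they are too few for a share under 0.05. There the real count of 381 was reached by 1 split and the highest other was 0, and the real count of 18 gene lists was reached by 1 split and the highest other was 16.

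A further pattern weighed was the rise of the immune list, which came with higher globin signals on 4 of 5 days. A lower share of neurons would raise the transcripts of every other cell type alike. The immune median exceeded that of 32 Müller glia, pigment epithelium and myelin genes in 5 of 5 pairs, by a mean log2 difference of 0.645 (SD 0.299). This argues against a lower share of neurons as the whole cause, but narrowly, since the bar was 2 SD. It also holds only if the 32 genes did not change per cell. That was not tested, and 4 of the Müller glia genes were themselves called as risen. The contrast with the 32 genes replaced the immune minus inner retinal one (0.954, SD 0.374). That first contrast was void because fewer neurons would themselves widen the gap. Over the 6 unlesioned retinas the immune median rose with log2 hbaa1 at a slope of 0.126 (SE 0.0443). Blood alone would need 0.374 on day 3, and the bound set beforehand was 0.187. This argues against blood as the cause of the rise when the gap to the bound has to exceed 1 SE, and would leave it open under the 2 SE first used. On days 2, 3, 5, 7 and 14 the immune ratios were 0.96, 0.95, 1.04, 0.89 and 0.22, and those of hbaa1 1.93, 2.53, 0.78, 0.60 and -0.78. The immune rise kept its size on days 5 and 7 at smaller hbaa1 ratios, but not with less hbaa1. The hbaa1 signal was 16023 and 15260 in the lesioned arrays of days 5 and 7, and 2417 and 5158 on days 2 and 3. The control signals of days 5 and 7 were already 9292 and 10021. The ratios of these days therefore cannot decide on blood. On day 14 the immune ratio was upward while that of hbaa1 was downward, in 1 pair read after it was seen. Among these values that pair alone goes against blood as the whole cause. A smaller contribution of blood stays open. More immune cells, or more immune transcripts per cell, in the lesioned retina also stay open and were not tested.

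The last pattern weighed was the separation of the arrays into 2 blocks of 6. A batch in labelling, hybridization or scanning is a candidate explanation. The GAPDH ratio, which was not used to find the blocks, was in the lowest array of block 1 still 2.83 times that of the highest in block 2. That ratio comes from RNA quality probe sets and is taken within an array. It therefore cannot tell such a batch from a difference in RNA quality between the samples, which was not tested. The hybridization controls do not come from the tissue. They were 1.43 times as bright in the dimmest array of block 2 as in the brightest of block 1. The blocks were cut from these same controls, so a gap above 1 was certain and does not test the day as a cause. Brain and the true control, which have no day, lay in block 1. For the probe sets of the tissue the day post-lesion and the block cannot be told apart among the day arrays, because 0 days had arrays in both blocks.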

How the results depend on the processing

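The tests with the array block, within 1 array block, with the GAPDH ratio and of list slopes without day 14 at an estimated correlation were chosen only after the data were seen, and all other settings here were chosen beforehand. Of the main counts under other settings, 122 lay within 1.5 times the count reported and 55 did not. The 122 include settings where nothing was called in either fit, all on single days or in the true control comparison. Such agreement says little about how stable the results are. Where no construction of the setting is named, the cause was not tested.

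The pairing by day decided the lesion count. Without this replicate block limma called 0 probe sets (351 at an unadjusted p under 0.05), and with all 6 unlesioned retinas and no block 2 (457). In the trend the fit without the block called 0 (17 at an unadjusted p under 0.05). For the gene lists of the lesion the unpaired fit passed 14, of which 13 were among the 18. The list tests of the trend also rest on the block and were not run without it. The block does not enter the by-day, brain or true control comparisons.

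The lesion count of 381 was 226 with the filter at the 60th percentile, which tests fewer probe sets, and 717 at an adjusted p under 0.10. It ranged from 165 (without day 7) to 573 (without day 14), was 0 in the pairs of block 1 (784 at an unadjusted p under 0.05 in limma), which are fewer, and 494 in those of block 2. Of the 12 leading rises and 12 leading falls, 12 and 5 were called whichever day was left out. Probe sets called without a day had the same sign on that day in 91.8%, 96.2%, 90.8%, 94.5% and 75.6% of cases for days 2, 3, 5, 7 and 14. With the GAPDH covariate 10 were called, while the medians went from 0.67 to 0.54 and from -0.50 to -0.37 with 100% and 98% of signs the same. There desi1a turned from -0.64 to 0.01 (0.0125, limma adjusted p = 0.997), the 1 sign change among the named genes that were called. Sign changes of named genes that were not called were not counted. Across the other settings the calls of the 52 named lesion genes that were called held in 497 cases and were lost in 222.

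The trend count of 10 was 6 with a pseudocount of 12.5, 4 with no filter, 6 with no intensity trend, and 0 by limma for early against late days (329 at an unadjusted p under 0.05). It ranged from 1 (without day 14) to 12 (without day 3). For the single days, a pseudocount of 12.5 gave 0 by limma on days 2 and 5 (249 and 382 at an unadjusted p under 0.05). On day 5 there were also 0 calls with no filter (621), with the filter at the 60th percentile (232) and with quantile normalization (375). A pseudocount of 200 gave 2 calls on each of days 3, 5 and 7, and an adjusted p under 0.10 gave 2 on day 7. Without the true control limma called 0 on days 2 and 5 (199 and 284 at an unadjusted p under 0.05), and without any 1 day control also 0 on both (203 to 333 and 304 to 500). The array block term gave 16, 8, 8 and 5 calls on days 2, 3, 5 and 7.

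The brain count of 1073 was 2261 with the array block term and 2666 within block 1. It ranged from 878 to 962 without 1 day control, was 816 without the true control, and ran from 1748 to 1901 with the block term and 1 retina of block 1 left out. The true control differed in 4 probe sets with the block term and in 38 within block 1, with 1 residual degree of freedom. With an estimated correlation, gene lists past camera went from 18 to 0 (5 at an unadjusted p under 0.05) for the lesion, from 11 to 0 (2) for the trend, also 0 without day 14 (0), and from 15 to 2 for brain, and fry passed 6 for the lesion. Probe sets under the filter lie near background, where the pseudocount limits what change can be seen.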

Other observations

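The tests of gene symbol families were chosen only after the result was seen, and the genes named in this part were chosen after their values were seen.

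Outside the fixed lists, 4 families of risen genes stood out by the first letters of their symbols. Interferon-induced genes rose in 4 of 5 measured cases, with ifi27.1 at log2 1.51 ± 0.20 (SE, 5 pairs), ifi27.2 at 1.09 ± 0.27, ifi30a, a lysosomal thiol reductase gene, at 0.76 ± 0.15 and ifi44d at 0.63 ± 0.16. The ratio of ifi27.2 was 0.19, 1.49, 2.16, 1.82 and -0.23 on days 2, 3, 5, 7 and 14. Cathepsins, the proteases of lysosomes, rose in 4 of 6 cases, with ctsla at 0.82 ± 0.13, ctsz at 0.81 ± 0.13, ctsba at 0.78 ± 0.12 and ctsa at 0.39 ± 0.10.

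Proteasome genes outside the proteasome list rose in 4 of 13 cases. They were the proteasome activator subunits psme1 (1.09 ± 0.16) and psme2 (0.84 ± 0.20) and the immunoproteasome subunits psmb12 (0.61 ± 0.15) and psmb10 (0.58 ± 0.14). The ratio of psme1 was 1.69, 1.21, 1.31, 0.91 and 0.32 on days 2, 3, 5, 7 and 14. Translation elongation factor symbols rose in 4 of 10 cases, with eef2b at 0.56 ± 0.12, eef1a1l1 at 0.56 ± 0.10, eef1b2 at 0.42 ± 0.11 and the kinase gene eef2k at 0.45 ± 0.10.

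It may be that gene families outside the fixed lists rise together after the lesion. In a one-sided Fisher exact test of 232 symbol stems over 4971 genes, of which 146 had risen, 4 stems passed an adjusted p of 0.05: ifi (0.000810), cts (0.00119), eef (0.0101) and psm (0.0241). The tubulin stem, with 3 of 12 risen, did not (adjusted p = 0.209). Genes are not independent, and the call of each gene rests on the pairing by day, so this remains a hypothesis found and tested on the same arrays.

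Besides the 6 named genes, the trend called pyya, the peptide YY gene, at -0.88 per doubling of the day and a further tuba1b probe set at -0.63. It also called 2 probe sets without a single gene symbol, at -1.55 and -1.03. The ratio of pyya was 1.94 on day 2, 0.02 on day 5 and -0.47 on day 14. The hbaa1 signal varied widely among unlesioned retinas: it was 1000 in the true control and 597.5, 849.6, 9292, 10021 and 6429 in the controls of days 2, 3, 5, 7 and 14.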
